A study of Mus musculus with 2 samples.

How the data were processed

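The samples were enteric neurosphere cultures from the small intestine of C57BL/6 Plp1::GFP mice aged 12 weeks, dissociated with Accutase, sorted as GFP-negative and run on the 10x platform. Each library came from 2 pooled mice, 1 library from females and 1 from males. The deposited values were raw UMI counts per gene and cell barcode, made by the authors with Cell Ranger on the mm10 build, with software version 3.0.2 per the file headers. Per barcode, the median was 28689 UMIs and 5741 genes in the female library and 27443.5 UMIs and 5635 genes in the male library, over 31053 listed genes. Only 4 barcodes were shared by the libraries.

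Cells were kept with at least 500 genes, at least 1000 UMIs and at most 20% mitochondrial UMIs, which removed 75 of 4505 female and 27 of 2870 male barcodes. Scrublet in scanpy 1.11.5 (expected rate 0.06, seed 1) then called 123 female and 39 male doublets, 2.78% and 1.37% of the passing cells, and these were removed. Of 7375 barcodes, 4307 female and 2804 male cells were kept. Counts were scaled to 10000 per cell and log transformed. Of 2000 highly variable genes, the 1785 outside the fixed gene lists were used for 30 principal components, 15 neighbours and Leiden clustering at resolution 0.6 (leidenalg 0.10.2, igraph 0.11.9), which gave 19 clusters over both libraries together. The fixed lists were thus kept out of the clustering.

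Clusters were named with fixed markers by a rule written after the data were seen. A marker counted in a cluster at 5 CPM or more and at least 25% of its highest level in any cluster, and the class with the highest share of its markers was taken if at least 3 counted. A cluster stayed unnamed if another class had more markers among its 10 leading genes. It also stayed unnamed if its median UMIs were under 0.333 times the library's and none of those genes was a marker. The markers, the gene lists, the tests, the rule for naming genes and most alternatives were fixed before the data were examined.

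Neuron-like and mesenchymal-like cells were compared on UMI counts summed per library and class. The edgeR 4.0.16 quasi-likelihood test in R 4.3.3 was used with TMM scaling, filterByExpr, the library as a block and Benjamini-Hochberg adjustment at 0.05. Glia-like, pericyte-like and mesothelial-like cells, the other classes with at least 30 cells in each library, were treated alike and summarised by list. Results are given for fixed-list genes, adjusted over all genes tested and adjusted over the list alone. The SE given with a log2 fold was its absolute value divided by the square root of its F statistic. This SE leans on the spread shared by all genes and does not show how far the 2 libraries differed for a gene. The genes named for neuron-like cells are the 2 highest and 2 lowest called members of each list with the same direction in both libraries, except where they had too few UMIs for a fold. Nos1, Vip, Calb2 and Tac1 were added as genes of the transmitter question.

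Female and male libraries were compared without a test. CPM of the class sums were compared on the log2 scale after adding 5 CPM, and ratios carry the exact conditional binomial 95% interval of 2 Poisson counts. The 12 highest and 12 lowest genes at 20 CPM or more in the higher library are named, leaving out predicted (Gm and Rik), mitochondrial and ribosomal symbols. Each list was placed by its median among 10000 random lists matched on expression. This percentile treats the members as independent and does not measure the spread between libraries. A list whose members vary together can thus be extreme with any difference between the libraries. Shares of cells carry exact Clopper-Pearson 95% intervals, and a count of 0 is given with the share of cells with a detected UMI that 3 counts would make. For detection of single genes every cell was thinned to 5000 UMIs and shallower cells were left out. Contrasts between neuron-like clusters were added after the data were seen.

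The steps were tested on simulated data with 50 genes changed at each fold. For neuron-like against mesenchymal-like cells, 19, 35, 44 and 49 genes were recovered at 1.5, 2, 4 and 8 times, with 17 unchanged genes called among 15697. For glia-like cells 17, 34, 40 and 43 were recovered, for pericyte-like cells 5, 21, 34 and 43, and for mesothelial-like cells 18, 31, 44 and 45. Far fewer genes were changed than the real contrasts called, and all genes had the same dispersion. These simulations thus do not cover scaling or false calls where most genes differ. For female against male, a list shifted 1.5 times reached percentile 100 in both classes. Of unshifted genes, 5.61% in neuron-like and 8.07% in mesenchymal-like cells had an interval that left out 1, and 0 and 2 of 21 unshifted lists fell outside the central 95%. These counts were drawn with counting error only, from a profile shared by both libraries.

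Alternatives covered cell filters, doublets, resolution, components, clustering of each library alone, DESeq2 1.42.0, scaling, low-count filters, the library block, thinning, pseudocounts of 1 and 20 CPM and leaving out each library. Chosen after the data were seen were another Leiden seed, library size alone, clusters weighted equally, and leaving out the 2 mesenchymal-like clusters with the highest Slpi. Gene sequences were taken from the GENCODE annotation of GRCm38. Symbols Ccn2, Ccn1 and Ero1a were absent under those names, and Aldoa, shared by 2 gene identifiers, was left out. Other software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, scikit-learn 1.9.0, anndata 0.12.19 and matplotlib 3.10.9.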

Results

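Enteric neurospheres are floating cultures grown from dissociated gut wall, in which neurons, glia and supporting cells of the enteric nervous system are kept together. Single-cell 3′ RNA counts were obtained from such cultures of the mouse small intestine after sorting for cells negative for a Plp1::GFP reporter. Plp1 encodes proteolipid protein 1 and is used as a marker of enteric glia, so the sort was aimed at the neurons and mesenchymal cells of the cultures. There were 2 libraries, each from a pool of 2 C57BL/6 mice aged 12 weeks, 1 of females and 1 of males. The female library held 4505 cell barcodes and 137669769 UMIs, with a median of 28689 UMIs per barcode. The male library held 2870 barcodes and 81952370 UMIs, with a median of 27443.5 per barcode. With 1 library per sex there were no replicates, so differences between the sexes compare these 2 libraries and carry intervals for counting error only.

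Genes of the sex chromosomes matched the labels in both libraries. Xist, the RNA that silences an X chromosome (X, 103460366 to 103483254 in GRCm38, the mm10 assembly), stood at 1158 CPM (UMIs scaled to a common library total) in the female library and was seen in 99.0% of its cells. In the male library it stood at 0.0749 CPM and in 0.214% of cells. The Y-linked helicase gene Ddx3y (Y, 1260771 to 1286629) showed 127 CPM and 81.3% of male cells, against 0.0380 CPM and 0.0232% of female cells. Uty and Kdm5d reached 28.2 and 19.7 CPM in the male library and stayed at 0.0608 and 0.00760 CPM in the female library. No UMI of Eif2s3y was found in 4307 female cells, which allows up to 0.0697% of cells with a detected UMI, and it was seen in 58.8% of male cells at 58.0 CPM. Tsix, the antisense partner of Xist, stood at 44.2 CPM in the female and 0.0125 CPM in the male library.

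The first question was which cells the sorted cultures held. Mesenchymal-like cells, defined by fibroblast genes such as Pdgfra, Col1a1 and Dcn, made up 76.6% of 4307 kept female cells (95% exact binomial interval 75.3 to 77.9) and 84.7% of 2804 male cells (83.3 to 86.0). Neuron-like cells, defined by Elavl4, Tubb3, Stmn2 and similar genes, made up 12.8% of the female (551 cells, 11.8 to 13.8) and 7.03% of the male library (197 cells, 6.11 to 8.04). Glia-like cells were 1.90% and 3.35%, mesothelial-like cells 2.51% and 1.498%, and pericyte-like cells 1.07% and 1.498% of the female and male library. Immune-like cells with B-cell genes were 1.74% of the female library and 0.178% of the male. Smooth muscle-like cells (0.371% and 0.749%) and endothelial-like cells (0.418% and 0.2496%) were also named. A cluster led by DNA replication genes such as Top2a and Rrm2, with a median of 2897 UMIs in its female and 44870 in its male cells, was left unnamed and held 2.58% and 0.749% of cells. No cluster was named as interstitial cells of Cajal, epithelium, striated muscle or adipocytes. All shares describe reporter-negative sorted cells. Median UMIs were 31116 and 28554 in mesenchymal-like cells and 21495 and 21390 in neuron-like cells of the female and male library. The mesenchymal-like share rested on which clusters were named, and fell to 48.7% in the female and 52.2% in the male library at a Leiden resolution of 0.3. The mesothelial-like class rested on this even more. No cells received that name without a cell filter, without the top 10% of doublet scores, at resolution 0.3 or with 15 components. The name went to 0.643% of female and 0.434% of male cells with the strict filter. With another seed, tried after the data were seen, the male share was the higher, 3.39% against 2.21%. With each library clustered alone, no male cell was named mesothelial-like, endothelial-like or immune-like, and no cell of either library smooth muscle-like.

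**Figure D1:**
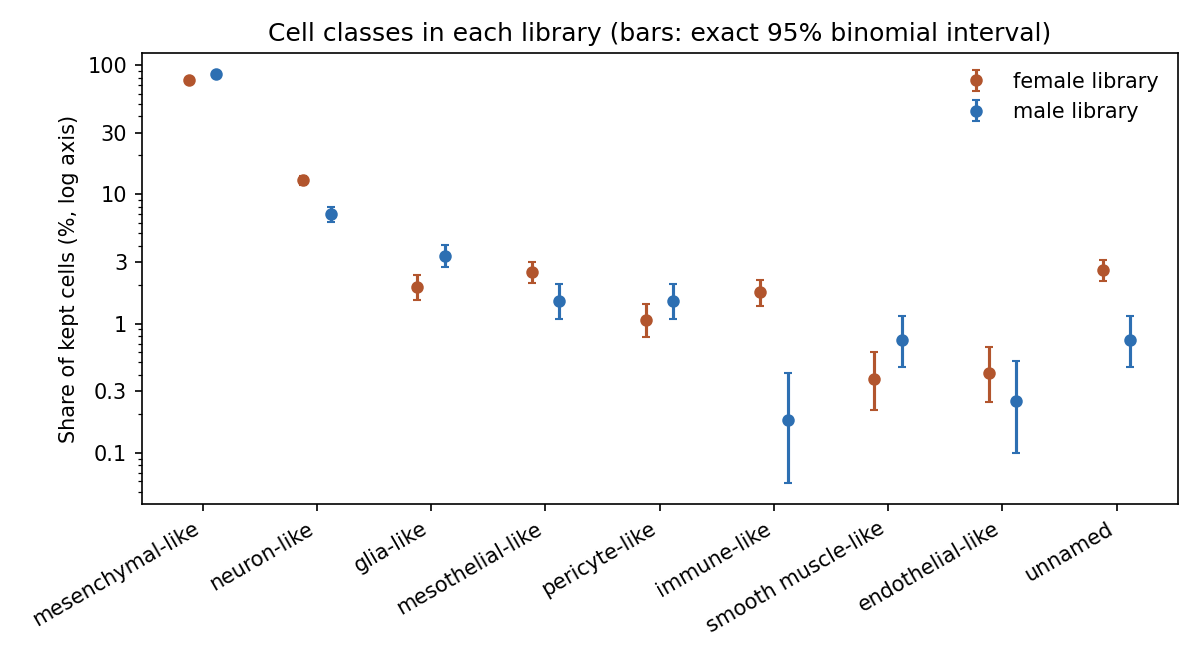
Share of kept cells (percent, log axis) in each class for the female and male library, with exact 95% binomial intervals that cover counting error only. Mesenchymal-like cells lie at 76.6% and 84.7%, and neuron-like cells at 12.8% and 7.03%.

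Cells with glial transcripts remained after the sort. Plp1, Sox10 and S100b were among the markers that named the glia-like cluster, so high shares there follow from the naming. In the glia-like cluster, Plp1 (X, 136822671 to 136839733) was detected in 98.8% of 81 female and 97.8% of 91 male cells after every cell was thinned to 5000 UMIs. Sox10, a transcription factor of the glial lineage, was detected in 64.2% and 68.1% of them, and S100b, a calcium-binding protein of glia, in 50.6% and 49.5%. Over all thinned cells, Plp1 was seen in 3.64% of the female library (3.09 to 4.25) and 4.80% of the male (4.04 to 5.67). Sox10 was seen in 1.36% and 2.31% and S100b in 1.40% and 1.95%. Mesenchymal-like cells, which should lack the gene, gave the background for Plp1, 1.34% and 1.40%, and neuron-like cells lay at 4.77% and 5.70%. With called doublets kept, male values were 0.639% in mesenchymal-like and 2.65% in neuron-like cells. Thinning left out 100 female and 35 male cells. Without thinning, Plp1 was seen in 10.1% of female and 9.84% of male cells, and in 7.76% and 6.19% of mesenchymal-like cells.

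The next comparison asked how neuron-like and mesenchymal-like cells of the same cultures differed in genes that had not been used to cluster them. The classes had been named by neuronal and fibroblast markers. Genes that vary together with these markers, such as axon and matrix genes, were likely to follow the naming, so their direction is not independent of it. Genes of neuronal function were the highest in neuron-like cells. All 20 tested genes of axons, cytoskeleton and synapses were higher there, led by the neurofilament gene Nefh (log2 fold 9.46, SE 0.25) and the microtubule gene Dcx of young neurons (8.29, SE 0.27). Of 21 ion channel and receptor genes, 19 were higher and 2 lower. The glutamate receptor gene Gria2 was 10.33 higher on the log2 scale (SE 0.29), and the sodium channel gene Scn9a had no UMI in mesenchymal-like cells. The 2 lower members were the stretch-gated channels Piezo2 (-4.85, SE 0.20) and Piezo1 (-2.95, SE 0.18). Of 24 transmitter and peptide genes, 19 were higher, among them Chat, which makes acetylcholine (9.31, SE 0.33), Nos1, which makes nitric oxide (9.16, SE 0.44), Vip (9.12, SE 0.30), and the calcium-binding protein gene Calb2 (8.35, SE 0.25). Cartpt was 9.84 higher (SE 0.29), at 1.497 CPM in female and 243 CPM in male neuron-like cells, against 0.00922 and 0.184 CPM in mesenchymal-like cells. Within single libraries its log2 ratio, after adding 5 CPM to both classes, was 0.38 in the female and 5.58 in the male. The added 5 CPM exceeded both female levels and so shrank the female ratio. Of the 4 lower members, Calca fell by 3.36 on the log2 scale (SE 0.30), Tac1 by 1.60 (SE 0.38), and Calcb had no UMI in neuron-like cells. Among 23 neurogenesis genes, 15 were higher and 6 lower. The proneural factor Ascl1 (9.59, SE 0.18) and the neuroendocrine factor Insm1 (8.96, SE 0.21) led the first group, and Hes1, a Notch target (-2.61, SE 0.22), and Etv5 (-2.34, SE 0.18) led the second. Apart from Tac1, adjusted p for the genes named with a fold here ran from 1.5e-10 to 3.5e-06, and it was 0.0034 for Tac1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjustment over 15697 genes).

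Matrix and signalling genes went the other way. All 22 extracellular matrix genes were lower in neuron-like cells, with Thbs1 at -6.50 (SE 0.22) and Col6a3 at -6.08 (SE 0.21). Of 18 matrix remodelling genes, 15 were lower, such as the protease Mmp3 (-6.24, SE 0.17), and 2 were higher, the protease Adamts5 (2.49, SE 0.29) and the inhibitor Timp3 (0.998, SE 0.09). All 12 tested genes of the TGF-beta response were lower, including Tgfbi (-6.01, SE 0.24) and Tgfb3 (-5.99, SE 0.21). Neurotrophic and guidance factors were mostly mesenchymal: 18 of 22 were lower in neuron-like cells, with Igf1 at -6.73 (SE 0.15) and no UMI of Fgf10. Sema3c, a guidance cue, was higher in neuron-like cells (3.16, SE 0.21), as was Nrg1 (0.91, SE 0.23), whose call was lost in DESeq2, without the library block and after thinning. Of 20 BMP and Wnt niche genes, 13 were lower, and Sfrp2 and Foxl1 had no UMI in neuron-like cells, although DESeq2 called neither. The 4 higher niche genes included the Wnt agonist Rspo2 (6.22, SE 0.37) and Bmp7 (3.71, SE 0.29). Of 13 genes of gut fibroblast subsets, 10 were lower, with no UMI of Ackr4, while the complement gene C7 was higher (3.86, SE 0.42). Inflammatory mediators were lower for all 19 tested genes, such as the cytokine Il33 (-6.26, SE 0.15) and the acute-phase gene Saa3 (-6.60, SE 0.25). Saa3 stood at 28100 CPM in female and 29900 CPM in male mesenchymal-like cells, and its 537 and 268 CPM in neuron-like cells were near the level seen in glia-like cells, 586 and 276 CPM. Leaving out Nrg1, the adjusted p of the genes with a fold in this group ran from 2.6e-10 to 2.8e-05 in edgeR with Benjamini-Hochberg adjustment.

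Stress, immune and growth genes were also mostly lower in neuron-like cells. Of 17 immediate early genes, which respond to dissociation, 16 were lower, with Klf4 at -5.42 (SE 0.12) and Nr4a1 at -4.47 (SE 0.12), and 17 were lower when adjusted over the list alone. Integrated stress response genes were lower for 15 of 17, such as Nupr1 (-5.29, SE 0.10) and the serine synthesis gene Phgdh (-4.31, SE 0.16), and Chac1 was higher (1.81, SE 0.27). Interferon response genes were lower for 16 of 17, led by Ifi44 (-7.02, SE 0.23) and Gbp2 (-5.59, SE 0.18). The exception, Ifit2 (0.53, SE 0.17), was not called by DESeq2. Antigen presentation genes were lower for 10 of 11, with H2-T23 at -3.10 (SE 0.14) and Tapbp at -2.63 (SE 0.13). Of 13 p53 target and senescence genes 11 were lower, such as Cdkn2b (-3.00, SE 0.16) and Gdf15 (-3.10, SE 0.34). Of 25 genes of G2 and M phase 22 were lower, with Hmmr at -4.91 (SE 0.37), and Ckap2 was higher (0.43, SE 0.15) with a call that DESeq2 did not make. Hypoxia genes were lower for 11 of 17, with the kinase Hk2 at -6.51 (SE 0.22) and the glucose transporter Slc2a1 at -3.41 (SE 0.18). The neuronal glucose transporter Slc2a3 was higher (3.63, SE 0.16), as was Bnip3 (1.05, SE 0.13). Cholesterol synthesis was the group of this kind that was mostly higher, for 11 of 15 genes, including Hmgcs1 (1.02, SE 0.08) and Dhcr7 (1.11, SE 0.13), with 3 lower, among them Dhcr24 (-0.60, SE 0.14). Dhcr24 turned to 0.21 without 2 mesenchymal-like clusters high in Slpi, a choice made after the data were seen. Of 6 tested steroid receptor genes 3 were lower, and the androgen receptor gene Ar fell by 4.39 (SE 0.26). Esr1 stood at 0.333 CPM in female neuron-like cells, with no UMI in male ones, and at 13.7 CPM in female mesenchymal-like cells. Gper1 was higher (1.84, SE 0.68) in a call that DESeq2 did not make. Of 4 genes that escape X inactivation, Ddx3x was lower (-0.82, SE 0.09; not called without the library block), and Kdm6a (0.43, SE 0.11) and Eif2s3x (0.41, SE 0.10) were higher without passing the threshold in DESeq2. S phase genes were called least often, 1 higher (Rrm1, 0.50, SE 0.13, not called by DESeq2) and 9 lower of 23, including Cdca7 (-3.36, SE 0.42) and Dtl (-2.10, SE 0.26). In edgeR with Benjamini-Hochberg adjustment, adjusted p for these genes ran from 1.5e-10 for Nupr1 to 0.035 for Gper1, and it was 0.0031 for Dhcr24.

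Across the X-inactivation and Y list and the 22 other lists together, 104 genes were higher and 239 lower of 385 tested. Over all 15697 genes, 5046 were higher and 5711 lower (edgeR, Benjamini-Hochberg adjusted p under 0.05). The model had 4 sums of cells, with the library as a block, and 1 residual degree of freedom before moderation across genes, so these calls lean on the spread shared by all genes. With library size alone as the scaling, chosen after the data were seen, the median log2 fold of all genes moved from -0.05 to 0.30. All genes then split into 6995 higher and 4408 lower, S phase genes into 5 higher and 5 lower, hypoxia genes into 5 higher and 9 lower, and cholesterol genes into 11 higher and none lower.

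**Figure D2:**
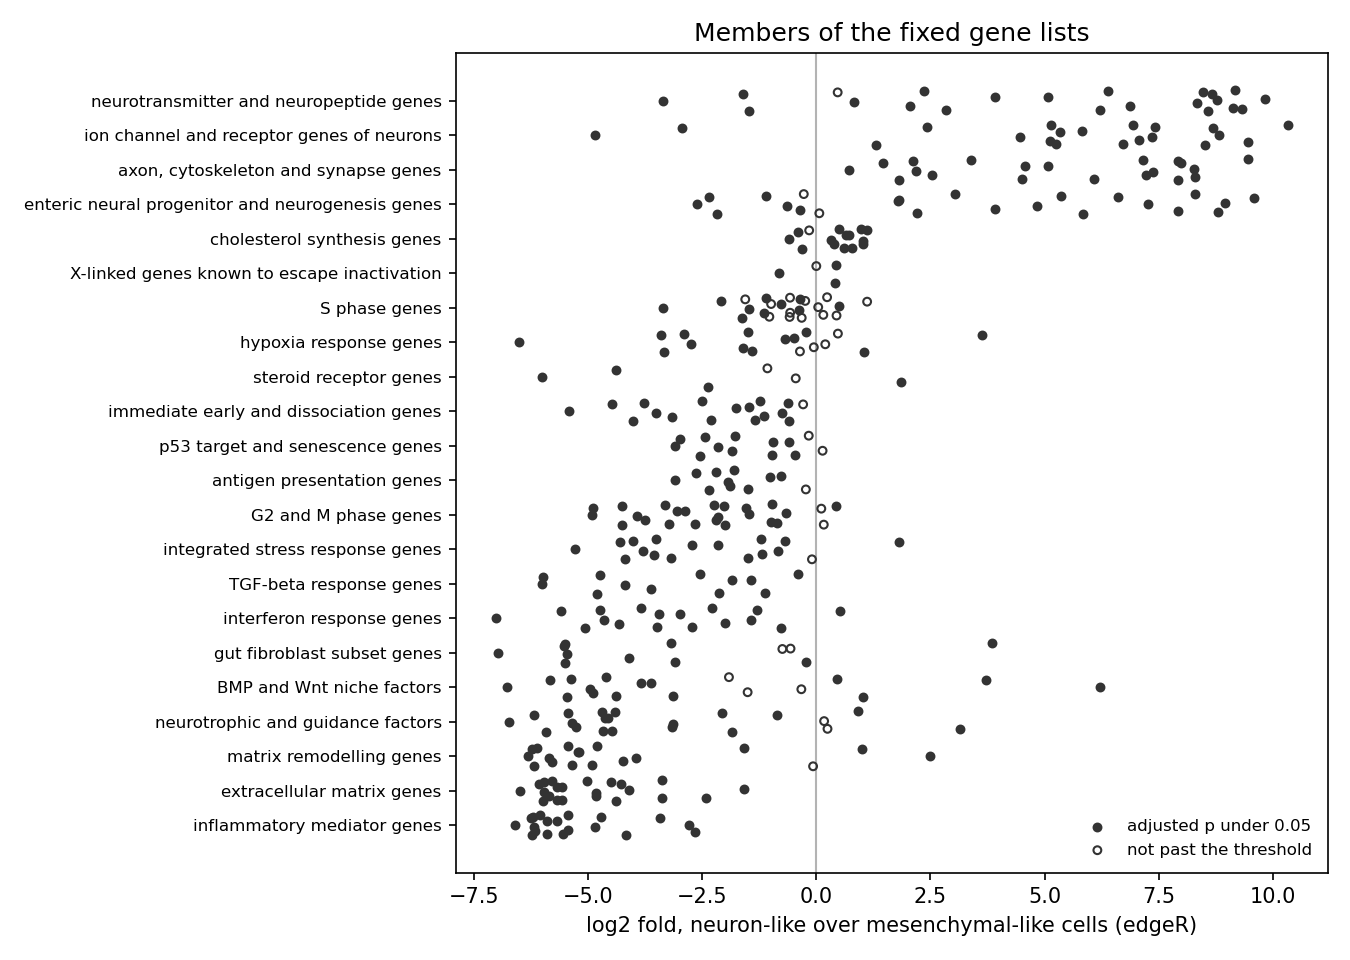
Fitted log2 fold of each tested gene of the fixed lists, neuron-like over mesenchymal-like cells, with filled points at a Benjamini-Hochberg adjusted p under 0.05 in edgeR and open points above it. Genes without a UMI in either class are left out of the plot. All 20 genes of axons, cytoskeleton and synapses lie above 0, and all 22 extracellular matrix genes lie below 0.

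Which transmitters the neuron-like cells carried was read from cells thinned to 5000 UMIs, 545 female and 193 male, after leaving out 6 and 4 shallower cells. Nos1 (chromosome 5, 117781032 to 117958840) was seen in 71.7% of female (67.8 to 75.5) and 70.0% of male cells (63.0 to 76.3). In mesenchymal-like cells it was seen in 1.47% and 0.510%. Chat (chromosome 14, 32408203 to 32465989) was seen in 21.7% of female (18.3 to 25.3) and 7.25% of male cells (4.02 to 11.9), against 0.0305% of female mesenchymal-like cells and none of 2353 male ones, which allows up to 0.127% of cells with a detected UMI. Slc18a3, which loads acetylcholine into vesicles, was seen in 38.4% (34.25 to 42.6) and 27.5% (21.3 to 34.33), with intervals that just overlapped, against 0.153% of female and none of 2353 male mesenchymal-like cells, which allows up to 0.127% with a detected UMI. Vip (chromosome 10, 5639218 to 5647617) was seen in 22.0% of female (18.6 to 25.7) and 42.0% of male cells (34.9 to 49.3), against 0.275% and 0.212% of mesenchymal-like cells. Galanin (Gal) was seen in 40.2% and 76.7%, against 3.12% and 2.38% of mesenchymal-like cells. Calb2 was seen in 13.03% (10.3 to 16.1) and 4.15% (1.81 to 8.004), against 0.0611% and 0.0425% of mesenchymal-like cells. Tac1, the substance P precursor gene, was seen in 0.551% and 0.518% of neuron-like cells and in 1.34% and 0.935% of mesenchymal-like cells. Without thinning, 140 female mesenchymal-like cells held 696 Tac1 UMIs, so for this gene they were no measure of background. Without thinning, at medians of 21495 and 21390 UMIs, the shares for female and male cells were 84.4% and 81.7% for Nos1, 47.6% and 17.3% for Chat, 70.8% and 45.2% for Slc18a3, 39.9% and 54.8% for Vip, and 23.2% and 9.14% for Calb2. Unthinned Tac1 was seen in 1.81% and 1.02%.

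These shares went in part with the 3 neuron-like clusters, which the libraries filled differently. Cluster 6, with the cholinergic genes, held 61.7% of female and 21.3% of male neuron-like cells. Cluster 8, with Nos1, Vip and Gal, held 20.9% and 52.3%, and cluster 13, with the Notch target Hes5, held 17.4% and 26.4%. Within cluster 6, Chat was detected in 32.2% of 335 female (27.3 to 37.5) and 26.8% of 41 male thinned cells (14.2 to 42.9), and Slc18a3 in 53.7% and 61.0%. Nos1 was detected in 66.6% and 68.3% of these cells, more often than Chat, so cluster 6 was not set apart by a lack of Nos1. Within cluster 8, Nos1 was detected in 99.1% and 91.1%, Vip in 63.5% and 67.3%, and Gal in 98.3% of female and all 101 male cells. In cluster 13, Nos1 was detected in 56.8% of female (46.3 to 67.0) and 29.4% of male cells (17.5 to 43.8), and without thinning in 74.0% (64.0 to 82.4) and 50% (35.8 to 64.2), where the intervals overlapped. Also in cluster 13, thinned shares were 14.7% and 5.88% for Vip and 14.7% and 3.92% for Slc18a3, with overlapping intervals, but without thinning the intervals lay apart, at 32.3% (23.1 to 42.6) and 5.77% (1.21 to 15.95) for Vip and 36.5% (26.9 to 46.9) and 7.69% (2.14 to 18.5) for Slc18a3. For Vip this ran against the direction over all neuron-like cells. In cluster 6, Vip was detected in 9.85% of female (6.88 to 13.6) and 24.4% of male cells (12.4 to 40.3), and in cluster 8, Slc18a3 in 13.04% (7.49 to 20.6) and 25.7% (17.6 to 35.4), with overlapping intervals. Without thinning these were 26.5% and 42.9% for Vip and 38.3% and 41.75% for Slc18a3. Nos1 and Vip were found in the same cell in 106 of 545 female cells, where independent detection would give 86.1, and in 71 of 193 male cells, where it would give 56.7. Chat and Nos1 were found together in 80 female cells (84.7 by independent detection) and 11 male cells (9.79).

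**Figure D3:**
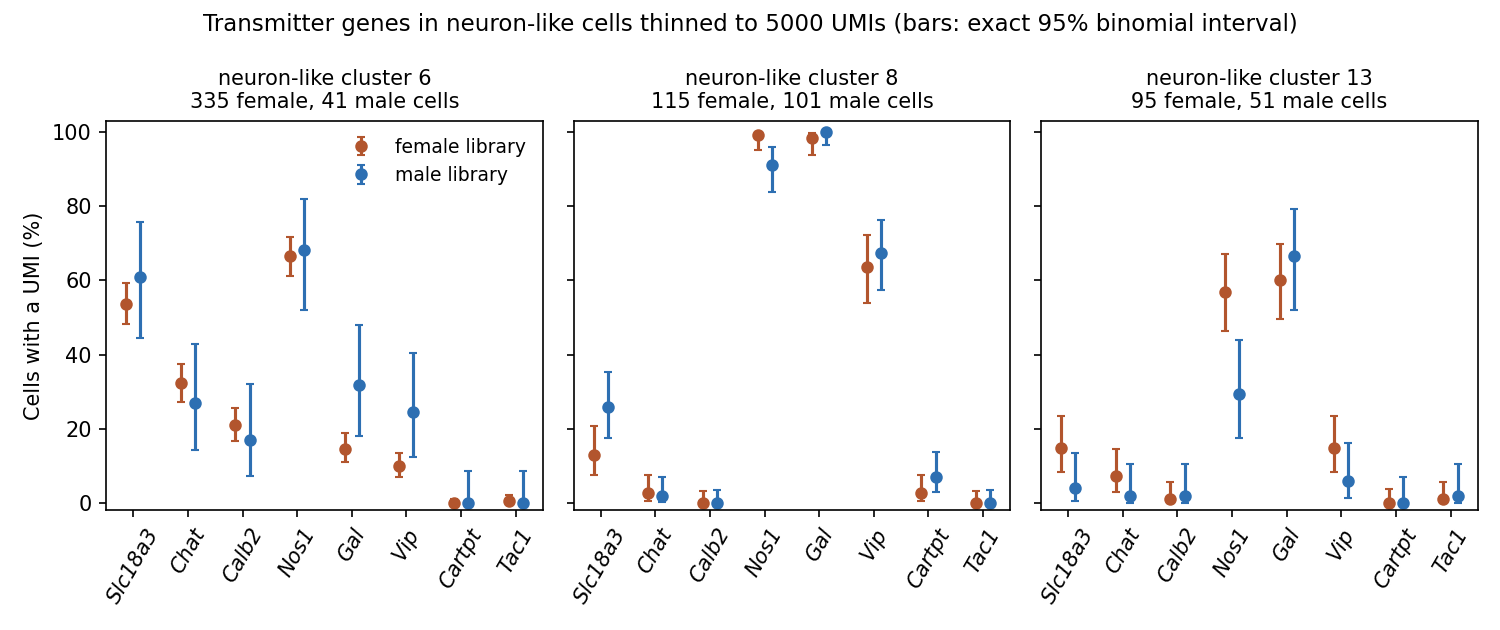
Share of thinned neuron-like cells with a UMI (percent) of each transmitter gene in clusters 6, 8 and 13, for the female and male library, with exact 95% binomial intervals that cover counting error only. Slc18a3, Chat and Calb2 are highest in cluster 6, where Chat lies at 32.2% and 26.8%, and Gal and Vip are highest in cluster 8.

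Between the libraries, mesenchymal-like cells differed in sex-linked genes, in genes with near-identical copies and in genes of single clusters such as S100a8. Some other named genes, such as Gsdme and Sft2d1, went the same way in all 9 mesenchymal-like clusters. Beyond Xist and Tsix, the named genes furthest up in the female library were Gstp1 (432 against 79.9 CPM, chromosome 19, 4035407 to 4037985) and Uba52 (599 against 132 CPM, chromosome 8, 70508263 to 70510801). Both share 3′ sequence with other annotated genes, so their counts are uncertain. Next came the X-linked gene Mid1, 3.12 times higher (95% counting interval 2.85 to 3.42), Ccdc85b (2.38 times), Usp2 (2.30 times), the protease gene Adamts9 (2.12 times), Rgs2 and Grcc10 (both 2.10 times) and Agbl3 (59.8 against 26.2 CPM). Thy1, one of the markers, stood at 20.8 against 7.99 CPM, a log2 ratio of 0.99 that was 0.41 with clusters weighted equally. Lower in the female library, after the Y-linked genes Ddx3y, Eif2s3y and Uty, were Rnaset2b (0.153 times), AY036118 (0.323 times), the growth factor gene Kitl (0.440 times, 0.417 to 0.464), Snhg9 (0.435 times), Sft2d1 (0.444 times), Gsdme (0.493 times) and Htra1 (0.496 times). With clusters weighted equally, log2 ratios shrank from 0.98 to 0.65 for Rgs2 and from -0.97 to -0.63 for Htra1. Those of Grcc10 and Gsdme stayed at 0.95 and -0.96. S100a8 (0.369 against 30.5 CPM) and Mmp3 (76.3 against 163 CPM) were also lower, with log2 ratios of -2.73 and -1.05. Both lead cluster 10, which held 63 female and 120 male cells, and their log2 ratios were -0.54 and -0.20 with clusters weighted equally. That cluster was named by 7 of 10 fibroblast markers, but none was among its leading genes, which also included Lyz2, Lgals3 and Fcer1g.

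Gene groups in mesenchymal-like cells were placed by the median log2 ratio of their members among 10000 random lists matched on expression. Extracellular matrix genes stood higher in the female library (median 0.19, percentile 99.98), with 16 members above and 5 below 0 and Postn furthest at 0.74. Matrix remodelling genes did as well (0.17, percentile 99.83), although their most extreme member was Mmp3 at -1.05. The 4 genes that escape X inactivation had a median of 0.64 (percentile 99.97), with Ddx3x at 0.82, and mitochondrial genes a median of 0.29 (percentile 100), with 9 members above and 3 below 0, mt-Atp8 furthest at -1.21, and a median share of mitochondrial UMIs of 3.13% in female and 2.28% in male cells. Inflammatory mediators stood lower in the female library (-0.24, percentile 0.01), with 14 of 17 members below 0 and Ccl2 at -0.69. The p53 target and senescence genes did too (-0.26, percentile 0.04), with 8 of 12 below 0 and Cdkn2a at -0.56. Axon genes reached percentile 98.29 on 3 members, with Ncam1 at 0.46, and left that range after thinning. The other 14 lists measured, X-inactivation and Y genes aside, lay within the central 95% of random lists.

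Female and male neuron-like cells came mostly from clusters 6 and 8 respectively, and the genes that differed most between the libraries included many that mark these clusters. Higher in the female library, after Xist and Tsix, were the opioid receptor gene Oprk1 (8.10 times, 5.39 to 12.8), Ndufa4l2 (5.08 times), Chat (3.93 times, 2.98 to 5.25), Plcxd3 (3.31 times), Fxyd7 (3.30 times) and Bnc2 (3.25 times). With clusters weighted equally, their log2 ratios shrank from 2.27 to 0.82 for Oprk1, from 2.21 to 0.87 for Ndufa4l2, from 1.65 to 0.69 for Chat, from 1.66 to 0.31 for Plcxd3, from 1.65 to 0.38 for Fxyd7 and from 1.60 to 0.69 for Bnc2. Adgre1 (5.25 times, 3.58 to 7.995) and Clu (4.56 times, 3.12 to 6.90) kept log2 ratios of 1.76 and 1.60 with equal weights. Clu also leads the mesothelial-like cluster. Some genes far higher in mesenchymal-like than in neuron-like cells, chosen after their values were seen, went the same way in clusters 6, 8 and 13, with log2 ratios of 1.67, 1.46 and 1.37 for C3 and 1.33, 1.47 and 1.11 for Col6a2, but Col5a2 went the other way (-0.10, -0.30 and -1.24). Of the lists that hold them, extracellular matrix genes had 6 members above and 4 below 0 (percentile 83.54) and inflammatory mediators 2 above and 3 below (percentile 50.08). Gstp1 (117 against 23.7 CPM) and Uba52 (441 against 105 CPM) were again higher and again uncertain. Lower in the female library, besides Ddx3y, Eif2s3y, Uty and Kdm5d, was first Cartpt (1.497 against 243 CPM), whose 1003 male UMIs lay in 9 cells. Pttg1 (0.0565 times, 0.0354 to 0.0866) and the peptide gene Cck (0.128 times, 0.0935 to 0.173) were lower in all 3 clusters, as were Hmcn1 (0.216 times), Ckb (0.268 times) and Slitrk6 (0.219 times). Hes5 (0.176 times) and the growth factor gene Areg (0.171 times) were lower in 1 of 3 clusters, and their log2 ratios moved from -2.37 to -0.50 and from -2.34 to -0.28 with equal weights.

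Among gene groups in neuron-like cells, X-inactivation and Y genes aside, neurogenesis genes stood lowest in the female library (median -0.80, percentile 0), with 14 of 20 members below 0 and Hes5 at -2.37. Immediate early genes (-0.40, percentile 0; Egr1 at -0.91), antigen presentation genes (-0.67, percentile 0.03; H2-T23 at -1.02), TGF-beta response genes (-0.48, percentile 0.07; Inhba at -1.47), p53 target genes (-0.30, percentile 0.05; Cdkn1a at -1.38) and S phase genes (-0.33, percentile 1.24; Mcm6 at -0.58) also stood lower. Ion channel and receptor genes stood higher (0.38, percentile 100), with 10 of 12 members above 0 although Gria2 lay at -0.82, and so did axon and synapse genes (0.23, percentile 99.97; Dcx at 1.09). Mitochondrial genes (0.43, percentile 100; mt-Co3, which has nuclear copies, at 1.23; median share of mitochondrial UMIs 4.42% in female and 2.96% in male cells), X-escape genes (0.51, percentile 99.93; Kdm6a at 0.63) and neurotrophic factors (0.37, percentile 99.55; Nrg1 at -0.88) were also higher. Transmitter genes had a median of -0.37 (percentile 0.01), which turned to 0.00645 with clusters weighted equally, and the 4 measured matrix remodelling genes a median of 0.21 (percentile 98.38; Adamts1 at 0.73), which turned to -0.04 after thinning. Ion channel genes fell to percentile 96.23 after thinning, and neurotrophic factors to percentile 80.53 with clusters weighted equally and 89.49 with no minimum CPM. With called doublets kept, the medians of TGF-beta, S phase, immediate early, antigen presentation and p53 target genes all returned to the central 95% of random lists. Some lists rested on few measured members: 4 of 11 for antigen presentation, 6 of 14 for TGF-beta, 5 of 23 for S phase and 6 of 24 for neurotrophic factors. Most lists measured in neuron-like cells lay outside the central 95%, so a place there does not set a list apart.

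Of the smaller classes, glia-like, pericyte-like and mesothelial-like cells were each set against mesenchymal-like cells by the same test, with 117 list genes higher and 172 lower, 75 and 82, and 74 and 145. The genes named for these classes were chosen after their values were seen. Glia-like cells had higher levels of cell cycle genes, 25 of 25 for G2 and M phase, such as Top2a (3.29, SE 0.15), and 16 of 23 for S phase. They were also higher for 18 of 22 neurogenesis genes, including Sox2 (9.80, SE 0.30) and the endothelin receptor Ednrb (6.99, SE 0.13), and for 8 of 11 antigen presentation genes. Gdnf, the growth factor that guides enteric neuron precursors, was 4.11 higher in glia-like cells (SE 0.30), at 35.6 and 37.1 CPM against 1.61 and 2.04. Pericyte-like cells were higher for 15 of 17 immediate early genes, such as Hspa1a (1.53, SE 0.17), and 8 of 17 hypoxia genes, and lower for 9 of 13 p53 target genes, such as Cdkn2a (-3.54, SE 0.32). They also had more of the basement membrane collagen gene Col4a1 (1.46, SE 0.17). Mesothelial-like cells were higher for 14 of 15 cholesterol synthesis genes, such as Ldlr (0.84, SE 0.11), 14 of 17 interferon response genes, such as Ifit1 (0.78, SE 0.11), and 10 of 11 antigen presentation genes. They were lower for 21 of 22 extracellular matrix genes, such as Col4a1 (-2.14, SE 0.09), and for 17 of 25 genes of G2 and M phase. DESeq2 called 110 higher and 148 lower for glia-like, 63 and 58 for pericyte-like, and 56 and 105 for mesothelial-like cells, and each class had fewer than 110 cells in either library. The calls for mesothelial-like cells hold for the clustering used here, since several other settings named no such cells.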

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

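The comparison of Hey1 between the libraries and the counts of rare classes below were looked at only after their values were seen.

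Hey1, a Notch target, went in opposite directions in the 2 libraries. Its neuron-like over mesenchymal-like ratio of CPM was 0.682 in the female library (counting interval 0.565 to 0.818) and 1.69 in the male library (1.37 to 2.05), and the difference was not tested. The TMM factors of the class comparison were 1.185 for male neuron-like and 0.867 for male mesenchymal-like cells. With these factors the directions were still opposite, but the male ratio was lower and its lower bound came close to no difference. Among neuron-like cells Hey1 was highest in cluster 13, at 45.6 CPM in the female and 93.9 CPM in the male library, and that cluster held 17.4% of female and 26.4% of male neuron-like cells.

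Cells of classes outside the comparisons were present above the limit that a count of 0 allows. Immune-like cells numbered 75 in the female and 5 in the male library, endothelial-like cells 18 and 7, and smooth muscle-like cells 16 and 21. The unnamed cluster held 111 female and 21 male cells.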

How the results depend on the processing

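Tests chosen after the results were seen were another Leiden seed, library size alone, clusters weighted equally and leaving out the 2 Slpi-high clusters. For all changes below the cause was not tested.

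The mesenchymal-like share of female cells was 78.96% without a cell filter, 80.98% with the strict filter, 64.28% without the top 10% of doublet scores, 48.69% at resolution 0.3 and 64.99% with 15 components. For male cells it was 86.63% with the strict filter, 83.15% with doublets kept, 71.15% without the top 10% of scores, 52.21% at resolution 0.3, 73.86% with 15 components, 51.82% with each library clustered alone and 82.81% with another seed.

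For neuron-like against mesenchymal-like cells, 698 values of named genes kept their direction and, where a test was made, their call, 21 lost the call and 1 turned, Dhcr24, to 0.209 without the Slpi-high clusters. Leaving the library out as a block gave 94 list genes higher and 222 lower. Within single libraries, 331 to 339 of 343 called list genes kept their direction.

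For female against male, 346 values of named genes stayed close, 158 moved and none turned. In neuron-like cells with no minimum CPM, the median was -0.06319 for transmitter, 0.04722 for neurotrophic, 0.03456 for matrix remodelling and -0.1515 for immediate early genes. With doublets kept it was -0.08991 for TGF-beta, -0.163 for S phase, -0.1604 for immediate early, -0.2335 for antigen presentation and -0.166 for p53 target genes. After thinning it was 0.1829 for ion channel, -0.03869 for matrix remodelling (turned) and -0.2814 for S phase genes. With clusters weighted equally it was 0.006452 for transmitter (turned), 0.1125 for neurotrophic, 0.1204 for matrix remodelling and -0.1895 for S phase genes. For axon genes in mesenchymal-like cells it was 0.0339 with no minimum CPM, 0.1782 after thinning and 0.09795 with clusters weighted equally.

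In neuron-like cells thinned to 10000 UMIs, shares were 33.97% for Chat, 79.32% for Nos1, 29.79% for Vip and 18.03% for Calb2 in the female library, and 76.84% for Nos1 and 50% for Vip in the male. Without thinning they were 47.55%, 84.39%, 39.93% and 23.23% for female cells and 17.26%, 81.73%, 54.82% and 9.137% for male cells, with Tac1 at 1.815% in female cells. With doublets kept, Nos1 was at 78.84% and Tac1 at 0% of male cells. Over all cells, Plp1 was seen in 5.368% of female cells at 10000 UMIs, and without thinning in 10.05% of female and 9.843% of male cells. Without thinning, Sox10 was seen in 2.322% of female and 3.459% of male cells and S100b in 2.438% and 4.137%, with S100b in 3.036% of male cells at 10000 UMIs. Xist was seen in 98.07% of female cells without a cell filter.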

Other observations

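The cluster contrasts and the tests of patterns in this part were chosen after the results were seen, except the test of dividing cells, which was set beforehand.

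The neuron-like cells held a group with progenitor genes, cluster 13. Against cluster 6, it was higher for 14 of 23 neurogenesis genes, with the Notch targets Hes5 (log2 fold 8.82, SE 0.30), Hes1 (5.18, SE 0.21) and Hey1 (3.90, SE 0.31), and lower for 14 of 19 axon and synapse genes, such as Dcx (-1.70, SE 0.20). Against cluster 8 it was higher for 16 of 22 neurogenesis genes, with Hes5 at 10.34 (SE 0.32), and lower for 16 of 20 axon and synapse genes, such as Nefh (-2.27, SE 0.22). Cholesterol synthesis genes were lower in cluster 13 for 13 of 15 against cluster 6 and 14 of 15 against cluster 8, such as Fdps (-1.90, SE 0.15, against cluster 8). Ascl1 was high in all 3 clusters, at 854, 880 and 663 CPM in female cells of clusters 13, 6 and 8. These genes were chosen after their values were seen, and male cluster 6 held 42 cells.

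Clusters 6 and 8 differed in transmitter and receptor genes, although Nos1 was detected in most cells of both. Cluster 6 was higher for Calb2 (6.93, SE 0.28), Chat (3.93, SE 0.25) and the transcription factor Phox2a (2.08, SE 0.10). Cluster 8 was higher for Gal, at 7230 against 105 CPM in female and 7786 against 239 CPM in male cells, for Ednrb (-4.67, SE 0.14 for cluster 6 over cluster 8), and for Npy, which had no UMI in cluster 6. It was also higher for 9 of 15 interferon response genes and 6 of 10 antigen presentation genes.

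Of 5234 genes compared outside the sex chromosomes, 7 differed in the same direction in all 12 clusters, with a mean log2 ratio of at least 1 over the clusters of each class: Gm10260, Gm11361, Gstp1, Uba52, Gm10076 and mt-Co3 were higher and Gm8797 lower in the female library. All 7 (100%, interval 59.0 to 100) shared 3′ sequence with another annotated gene, against 8.09% of genes compared. Different proportions of the clusters were weighed on the 9 genes with a class log2 ratio of at least 1 alike in both classes. For these 7 with Kitl and AY036118, the values within single clusters were a median 0.996 times those of whole classes (interval 0.972 to 1.015). This met the bound set against that explanation. But the 7 had been picked for differing in every cluster, so the median was largely set by the choice. Of the genes not picked that way, AY036118 lay at 1.015 and Kitl at 0.574. Reads of near-identical copies being assigned differently in the 2 libraries may be the cause. Sex, the pool of mice or other differences between the 2 libraries, with 1 library per sex, stayed open and untested.

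The female library held more cholinergic neuron-like cells. The lower bound of the female share in cluster 6 was 57.5%, above the male upper bound of 27.7%, which argued against counting error. Over all neuron-like cells, without the clusters or thinning, the female lower bounds for Chat and Slc18a3 lay at least 14.4 percentage points above the male upper bounds, which argued against cluster borders. Median UMIs of 21495 and 21390, Chat after thinning (18.3% against 11.9%) and CPM ratios with lower bounds of 2.98 for Chat and 1.83 for Slc18a3 argued against depth, although the thinned intervals of Slc18a3 overlapped (34.25% against 34.33%). Sex or the pool of mice could be behind the difference, and with 1 library per sex these cannot be told apart.

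Mesenchymal-like cluster 4 was led by imprinted genes, with Dlk1 at 706 CPM against 26.3 CPM in other mesenchymal-like female cells and 633 against 31.8 CPM in male cells. Fewer dividing cells stayed open. G2 and M phase genes stood at percentile 0 in both libraries against all other mesenchymal-like cells. They stood at 89.9 in the female and 75.1 in the male library once the cycling cluster was left out. Leaving it out takes the dividing cells out of the reference and made the bound set beforehand a wrong one. S phase genes stood high against all other mesenchymal-like cells, at 99.77 in the female and 99.98 in the male library. But the unnamed cluster led by DNA replication genes, whose best class was mesenchymal-like (8 of 10 markers), was not among those cells. S phase genes thus cannot decide whether cluster 4 held fewer dividing cells. Depth stayed open. Other imprinted genes also stood at percentile 99.97 or more in cluster 7, which was nearest in median UMIs, and this met the bound set for depth. But a single such cluster cannot tell depth from other traits that it shares with cluster 4, and CPM were already scaled to total counts. No other biological explanation was tested. The 17 other imprinted genes stood at percentile 100 in both libraries, which goes against a chance pick of leading genes, but some had shaped the clusters, and the 8 that had not stood at 99.29 in the female and 86.5 in the male library, so chance stayed open.

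Saa3 in neuron-like cells was close to its level in glia-like cells in both libraries, and whether it came from RNA of other cells was not tested.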
